A study of Arabidopsis thaliana with 13 samples.

How the data were processed

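Transcript levels of Arabidopsis thaliana were given in 13 profiles from Affymetrix ATH1 arrays, hybridised with biotin-labelled RNA made from total RNA. Empty vector replicates 1 and 2 of both induction sets were treated as the same hybridisations normalized in each set. In the induction experiment, 3-week-old seedlings carrying an estradiol-inducible ANAC092 construct (3 arrays), an estradiol-inducible ANAC059 construct (2 arrays) or the empty inducible vector were treated with 10 µM estradiol for 5 h, and shoots were collected. In the second experiment, leaf 11 of 38-day-old soil-grown plants was taken from wild type, from a line with a T-DNA insertion in ANAC059 and from a line with a T-DNA insertion in ANAC092, with 1 array each. Samples were grouped by their titles, which call the arrays of the inducible lines biological replicates.

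The deposited values are log2 signals made by the authors with RMA (background correction, quantile normalization and probe set summary), per the submitters' processing notes and the sample descriptions; the software version is not given in the sources used here. Per the labels, RMA was run on 3 separate sets of arrays. The ANAC092 set held 3 induced and 3 empty vector arrays, the ANAC059 set held 2 induced and 2 empty vector arrays, and the leaf set held 3 arrays. Levels were therefore compared only within a set, and no model was fitted across sets. Quantile normalization gives the arrays of a set nearly the same distribution, so a change shared by most transcripts would not be visible. Array medians were 7.55 to 7.71 on the log2 scale in the ANAC092 set, 7.59 to 7.62 in the ANAC059 set and 5.73 to 5.83 in the leaf set. The array number limits the precision, and no detection calls or scanner intensities were used.

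The table held 22810 probe sets. After 64 control probe sets were left out, 22746 were tested. Gene names came from the platform annotation paired with the probe sets, and locus identifiers from a gene table of assembly TAIR10.1, used for names only. Under this annotation 13513 probe sets had 1 gene, 503 had several and 8730 had none; 13436 of the single-gene probe sets matched a locus, 77 did not, and 13286 genes had at least 1 probe set. No probe set was named from an annotation with several genes. Neither ANAC092 nor ANAC059 had a probe set of its own under this annotation, so the level of the induced or disrupted gene was not examined and the sample labels were not checked in that way. The build behind the array design is not given in the sources used here, and no coordinates are reported.

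Induced and empty vector arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided), with Benjamini-Hochberg adjustment over all 22746 probe sets and a threshold of 0.05 on the adjusted p. Errors given with changes are the moderated standard errors of limma. Gene lists were tested with camera in the same fit, with a preset inter-gene correlation of 0.01 and again with an estimated correlation, using for each gene the probe set with the highest mean and lists of at least 5 measured genes. The 20 lists fixed before the data were examined named 268 genes, of which 35 had a probe set of exactly 1 gene under this annotation. Only the photosynthesis list reached 5. The other genes are called not measured, although the 8730 probe sets without a name may hold them. A further 23 lists were assembled after the fold changes had been seen: a list of low-oxygen response genes and 22 gene families defined by symbol. Their results are not independent of the data that prompted them. Each induction was tested on 24 lists, of which 1 is not reported here.

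Genes named in the text follow a rule fixed before the data were examined. For each induction it took the 12 highest and 8 lowest changes past the threshold among probe sets of 1 gene whose induced arrays all lay on one side of all control arrays, up to 4 passing members of each fixed list, and the measured members of a list of ANAC092 targets from earlier work. In that list AT3G13672 was entered as SINA1, while the gene table gives SINA2 as its synonym, so it is named by locus. For each T-DNA line it took the 8 highest and 8 lowest differences to wild type among probe sets of 1 gene whose higher value was at least 5.76, the median of all values of the leaf set. Genes named outside this rule were chosen after their values were seen, including members of a list given as not passing. The 2 highest and 2 lowest called probe sets without a name in each induction are also outside it, added after the data were examined.

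Overlap between the inductions was set against the number expected for independent lists. The correlation and covariance of the changes were set against 20 simulated draws of unchanged groups sharing control arrays. The departure of empty vector replicate 3 at ANAC059 calls was set against 20 such draws. Leaf differences were not tested, since each line had 1 array; list medians in the leaf set were ranked among 10000 random lists of equal size matched on mean level. Shares carry exact Clopper-Pearson 95% intervals, which treat probe sets as independent although they are not.

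The fits were tested on simulated data with the control means and the moderated spreads of the probe sets of each set. With the ANAC092 layout, 93% of probe sets changed by 1 on the log2 scale and 100% of those changed by 2 were recovered, with 15 false calls among 22746 probe sets. With the ANAC059 layout, 100% were recovered at both sizes, with 13 false calls. For lists shifted by 0.5 over 13286 genes, 10 of 10 were called in both layouts, and 1 of 10 unshifted lists was called with the ANAC092 layout and 0 of 10 with the ANAC059 layout. Simulated genes were independent, so these figures do not cover correlated genes or arrays.

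The alternatives were median centring, quantile normalization over the arrays of a fit, removal of the dimmest 33.3% of probe sets, a trended robust prior, array weights, single-gene probe sets only, replicate number as a block, each array left out in turn, other thresholds and other ways of combining probe sets. After the data were seen, fits with empty vector replicate 3 as the only ANAC092 control, with empty vector replicates 1 and 2 as the only ones, and with ANAC092 induced replicates 1 and 3 averaged were added. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.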

Results

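The series was designed to identify early target genes of ANAC092 and ANAC059, a pair of closely related NAC transcription factors known to promote leaf senescence. Estradiol was used to switch on each factor for 5 h in shoots of 3-week-old seedlings, with estradiol-treated empty vector plants as the control, and leaf 11 of 38-day-old T-DNA insertion lines was compared with wild type. The induction arrays comprised 3 ANAC092 induced and 3 empty vector arrays normalized together, and 2 ANAC059 induced and 2 empty vector arrays normalized together. The leaf set held 1 array of each genotype, without replicates. Neither ANAC092 nor ANAC059 had a named probe set, so the levels of the induced and disrupted genes were not examined.

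Arrays of a group were not equally close. ANAC092 induced replicates 1 and 3 differed from each other with an SD of 0.129 across probe sets on the log2 scale, against 0.364 and 0.343 from replicate 2. Empty vector replicates 1 and 2 differed with an SD of 0.178, against 0.386 and 0.351 from replicate 3. Empty vector replicates 1 and 2 of the ANAC059 set were treated as the same hybridisations as those numbered 1 and 2 in the ANAC092 set, since the difference between replicates 1 and 2 correlated at 0.883 across probe sets between the sets, and same-numbered arrays differed with an SD of 0.142 after separate normalization. The distance between ANAC092 induced replicates 1 and 3 was close to that between 2 normalizations of 1 array (0.125 against 0.122 and 0.120 after removal of a trend with signal level). The former lies within a single normalization, where the same hybridisation would not differ, so the distances are not of the same kind. If ANAC092 induced replicates 1 and 3 share an RNA sample, which was not tested, p-values that count them separately are too small.

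After ANAC092 induction, AT4G18425 rose 31.6-fold (log2 4.98 ± 0.13 SE, n = 3 per group, adjusted p = 5.97e-06), and AT4G04460, the aspartic protease PASPA3 of developmental cell death, rose 31.5-fold (log2 4.98 ± 0.17, adjusted p = 1.39e-05). SAG29, a SWEET-family sugar transporter gene used as a senescence marker, rose 23.4-fold from a mean log2 signal of 8.03 ± 0.42 (SD) to 12.57 ± 0.06 (SD), with an adjusted p of 4.76e-05. The chitinase gene ChiC rose by 3.97 on the log2 scale, the purple acid phosphatase gene PAP20 by 3.74 and the serine carboxypeptidase-like gene scpl48 by 3.69. AT1G62760, AT3G13672, AT1G20180 and AT2G44260 rose by 4.39, 4.34, 4.07 and 3.28, AT5G39520 rose 18.4-fold and AT2G14095 rose 17.1-fold.

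Among probe sets without a gene name, 257944_at rose by 6.14 and 257943_at by 5.41, and 253416_at and 263231_at changed by -2.29 and -2.08. The 12 named genes with the highest changes and these unnamed probe sets passed the threshold in each of the 6 fits that left out 1 array. With empty vector replicate 3 as the only control, the falls of the unnamed probe sets were of similar size (-2.23 and -1.92) but missed it (adjusted p 0.0513 and 0.0798), the lone array being assumed to vary like the induced ones.

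Falls were smaller than rises. AT3G10040, which the gene table also lists as HRA1 (hypoxia response attenuator), changed by -1.66 ± 0.11 SE (adjusted p = 0.000356), AT5G26200 by -1.59, AT5G19120 by -1.55 and AT3G27220 by -1.28, and these passed in all 6 fits that left out 1 array. AT3G07310 changed by -1.36, and its adjusted p ranged from 0.00638 to 0.0618, the latter without empty vector replicate 1. UGT76B1, a glycosyltransferase gene, changed by -1.27 and missed the threshold without empty vector replicate 1 or 2 (adjusted p 0.0230 to 0.0545 over the 6 fits). AT1G21680 changed by -1.34 and missed it without empty vector replicates 1 or 2 or induced replicate 3 (0.0118 to 0.106). SUFE2, a gene of iron-sulfur cluster assembly, changed by -1.30 and missed it without empty vector replicates 1 or 2 or induced replicates 2 or 3 (0.0270 to 0.144). With induced replicates 1 and 3 averaged SUFE2 missed it too (limma adjusted p 0.0645). With empty vector replicate 3 as the only control, AT5G19120, AT3G07310, AT1G21680, SUFE2 and UGT76B1 changed by -1.28, -1.33, -1.24, -0.91 and -1.47 and missed the threshold (adjusted p 0.0843 to 0.212).

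In all, limma called 507 of 22746 probe sets, 318 higher and 189 lower, and 226 of them by at least 1 on the log2 scale (177 higher, 49 lower). Of the called probe sets, 240 carried a single gene name. The groups did not overlap at 20.4% of probe sets, against 10% by chance. Without single arrays the count was 219 (empty vector replicate 1), 209 (empty vector replicate 2), 787 (empty vector replicate 3), 241 (induced replicate 1), 346 (induced replicate 2) or 234 (induced replicate 3). It was 242 with induced replicates 1 and 3 averaged as 1 replicate, all of them among the 507. With empty vector replicate 3 as the only control, 698 were called, 93.6% of them higher, and 175 were among the 507.

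**Figure D1:**
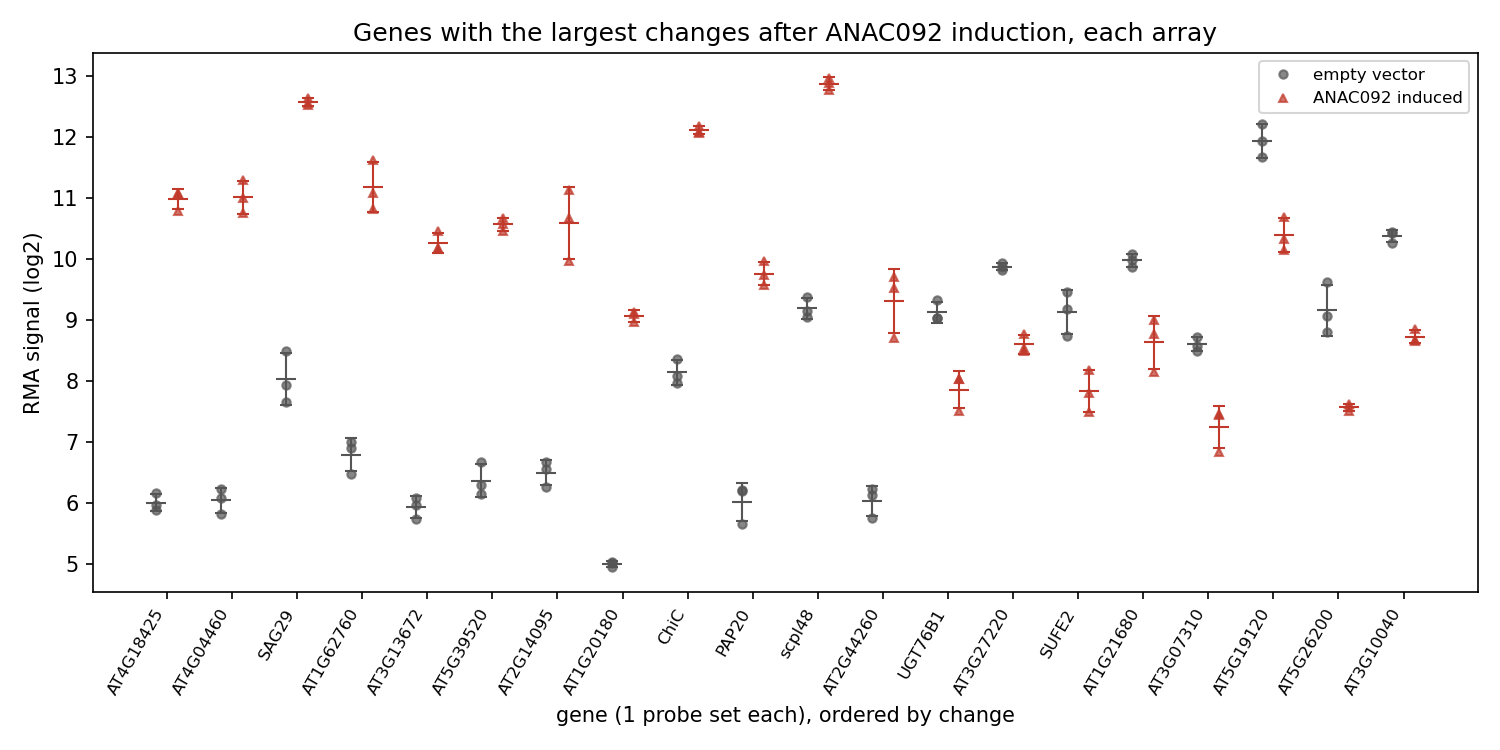
RMA signal on the log2 scale (y axis) of the 12 genes with the highest and the 8 with the lowest changes after ANAC092 induction (x axis); points are single arrays (n = 3 per group), horizontal marks are group means and bars are 1 SD. The induced arrays lie wholly above or wholly below the empty vector arrays for each gene, as the selection rule requires; SAG29 goes from a mean of 8.03 to 12.57.

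Few genes of the fixed lists had a probe set named for them alone under this annotation, and the others were not examined. Of 4 measured leaf senescence markers SAG29 rose; WRKY6 (-0.68, adjusted p = 0.0656), WRKY53 (0.38) and SAG101 (0.21) did not pass over all probe sets, and adjusted over the list alone 1 was higher and 1 lower. Of 4 measured nucleases and proteases of cell death, AT4G04460 and the vacuolar processing enzyme gene ALPHA-VPE rose, the latter by 2.38 ± 0.23 SE (2.35 with an adjusted p of 0.0753 with empty vector replicate 3 as the only control), and BETA-VPE (-0.08) and GAMMA-VPE (-0.17) did not pass; adjusted over the list alone 2 were higher. Both measured members of a list of ANAC092 targets from earlier work, SAG29 and AT3G13672, rose, also when adjusted over the list alone. That work may have used these arrays, so the list is not independent evidence of its direction. AT5G48570, the immunophilin gene ROF2 of the heat response, changed by -0.77. It missed the threshold without empty vector replicate 1 or 2 or induced replicate 1 or 3 (limma adjusted p 0.0376 to 0.106). With induced replicates 1 and 3 averaged it missed it too (0.066). As the 1 measured heat shock gene it was lower adjusted over the list alone. PPDK, a pyruvate orthophosphate dikinase gene, changed by -0.60 (adjusted p = 0.0427). It passed in 0 of 6 fits that left out 1 array (limma adjusted p 0.0659 to 0.206). As the 1 measured nitrogen remobilisation gene it was lower adjusted over the list alone. In a list of 1 measured gene this leaves the p unadjusted, and in limma 2734 of 22746 probe sets had an unadjusted p under 0.05.

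No member of the other measured fixed lists passed over all probe sets. These were abscisic acid and osmotic stress (4 measured, 1 higher adjusted over the list alone), oxidative stress (3, with 1 higher adjusted over the list alone), auxin response (3, with 1 higher adjusted over the list alone), jasmonate (2), chlorophyll breakdown (2), and 1 gene each for ethylene, cell wall loosening, the circadian clock and root markers, with 0 adjusted over the list alone in these. NAC factors, salicylic acid and defence, secondary wall and xylem, floral and dividing cell markers had no member with a named probe set under this annotation.

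The photosynthesis list, with 6 measured genes, moved lower as a set after ANAC092 induction (median log2 change -0.28, camera adjusted p = 0.0346; adjusted p = 0.572 with an estimated correlation). None of the 6 passed over all probe sets and 2 were lower adjusted over the list alone. The phosphoribulokinase gene PRK was at -0.65 and the protochlorophyllide oxidoreductase gene PORB at -0.42, both named after their values were seen. The call held only without induced replicate 1 among the 6 fits that left out 1 array (adjusted p 0.00633 to 0.107), and was lost when dim probe sets were removed (0.0650).

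Of the 23 lists assembled after the data were seen, 7 were called after ANAC092 induction. Genes encoded in the chloroplast were higher (69 measured, median 0.42, camera adjusted p = 2.35e-19; adjusted p = 0.183 with an estimated correlation). Of these, atpA rose by 1.87 ± 0.31 SE, ndhJ by 0.97, rpl20 by 0.91, matK by 0.85 and rbcL, the large subunit of Rubisco, by 0.75, and 64 did not pass; these 5 were named after their values were seen. The actin control probe sets, whose 3' minus 5' signal rises as RNA is degraded or labelling shortens, stood at 1.01 ± 0.07 (SD) on the induced arrays and 0.842 ± 0.08 (SD) on the empty vector arrays. In the ANAC059 set this signal was 1.01 and 1.06 on the induced arrays and 0.779 and 0.880 on the empty vector arrays. The GAPDH control probe sets did not show this shift. Their 3' minus 5' signal was 0.129, 0.177 and 0.254 on the ANAC092 induced arrays and 0.509, 0.0655 and -0.140 on their controls. In the ANAC059 set it was -0.00625 and 0.0571 on the induced arrays and 0.452 and 0.0300 on the empty vector arrays.

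Autophagy genes were higher (10 measured, median 0.41, camera adjusted p = 0.00174; adjusted p = 0.572 with an estimated correlation). APG8A rose by 1.23 ± 0.16 SE and ATG8H rose as well (adjusted p = 0.0439), both of the ubiquitin-like ATG8 family that coats autophagosome membranes, and 8 did not pass. Without empty vector replicate 3 the list's mean change was 0.15 and its adjusted p 0.181. SWEET sugar transporters were called higher (15 measured, median 0.05, mean 0.53, adjusted p = 0.0346; adjusted p = 0.572 with an estimated correlation) through SAG29, SWEET7 (1.95) and SWEET2 (1.94), with 12 not passing; the call was lost without empty vector replicates 2 or 3 or induced replicate 3 (adjusted p 0.00252 to 0.280 over the 6 fits). RALF-like peptide genes (10 measured, median 0.27, camera adjusted p = 0.0346, or 0.583 with an estimated correlation) had 0 passing members in limma. Their call was lost without empty vector replicate 3 or induced replicate 2 (camera adjusted p 0.00523 to 0.430 over the 6 fits). The list's mean change of 0.27 ranged from 0.12 to 0.37 over these fits.

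UDP-glycosyltransferases were lower (47 measured, median -0.08, adjusted p = 0.0194; adjusted p = 0.572 with an estimated correlation), with 6 members falling, among them UGT73B4 (-0.91) and UGT73B5 (-0.90), and UGT76D1 rising by 0.72. That call was lost without empty vector replicates 1 or 3 or induced replicates 1 or 3 (camera adjusted p 0.000307 to 0.0860). It was also lost with induced replicates 1 and 3 averaged (0.0503). TBL wall acetylation genes (22 measured, median -0.13, camera adjusted p = 0.0346, or 0.572 with an estimated correlation) had 0 passing members. Their call was lost without empty vector replicate 3 or induced replicate 3 (camera adjusted p 0.0277 to 0.218). It was also lost with quantile normalization (0.0529) and with induced replicates 1 and 3 averaged (0.0628). The genes of these families were named after their values were seen.

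Low-oxygen response genes, induced in plants when oxygen is short, were lower after ANAC092 induction (26 measured, median -0.79, camera adjusted p = 6.98e-14; adjusted p = 0.572 with an estimated correlation), and 5 members fell. The size of the difference depended on the control array. Relative to the mean of empty vector replicates 1 and 2, the list median was -0.99 in empty vector replicate 3 and -1.07, -1.17 and -1.10 in ANAC092 induced replicates 1, 2 and 3. With empty vector replicate 3 as the only control the mean change was -0.19 (adjusted p = 0.215), in a fit where that lone array was assumed to vary like the induced ones. For 17 members that had not been seen among the most changed genes, the medians were -0.95 in empty vector replicate 3 and -0.80, -0.97 and -0.97 in the induced arrays. The 5 called members, AT3G10040, AT3G27220, AT5G26200, AT1G26270 and AT1G74940, differed from replicate 3 by -1.71, -1.27, -1.23, -1.07 and -0.59; AT1G26270 and AT1G74940 were named after their values were seen. Replicate 3 was among the controls that gave these calls.

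**Figure D2:**
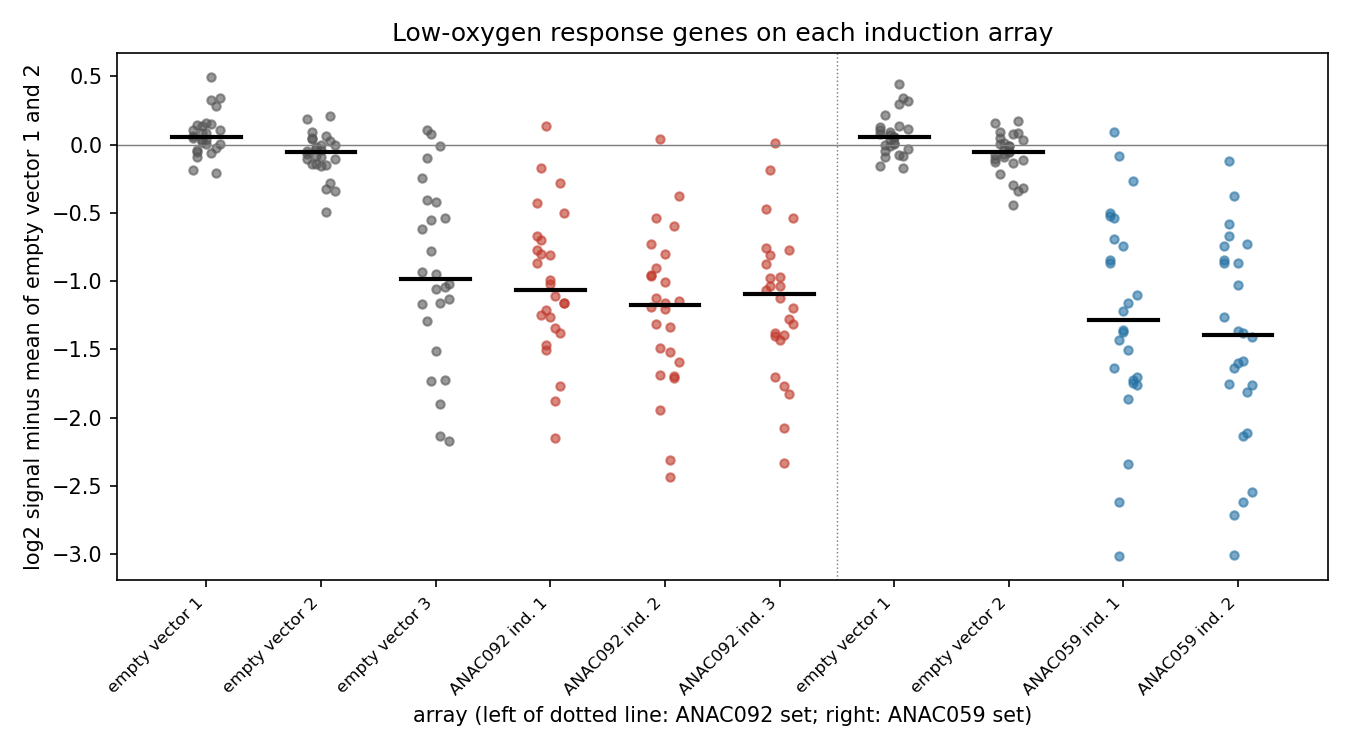
Log2 signal of 26 low-oxygen response genes on each induction array, minus the mean of empty vector replicates 1 and 2 of the same set (y axis), by array (x axis); points are genes and black lines are medians. Empty vector replicate 3 has a median of -0.99, close to the -1.07 to -1.17 of the ANAC092 induced arrays, and the ANAC059 induced arrays lie at -1.29 and -1.39.

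After ANAC059 induction, most of the named rises were of genes the annotation gives by locus only. AT5G17350 rose 3.11-fold (log2 1.64 ± 0.16 SE, n = 2 per group, adjusted p = 0.00561), AT1G77640 by 1.56 ± 0.12 SE, AT4G39670 by 1.42, AT3G01830 by 1.39 and AT5G39670 by 1.37 on the log2 scale. AT2G32190, AT4G27280, AT5G50915, AT1G35210, AT5G66650, TRM28 and IQD24 rose by 1.29, 1.26, 1.21, 1.14, 1.14, 1.14 and 1.13. The highest rise was that of 258059_at, a probe set without a gene name, by 3.81 ± 0.24 SE, and 251336_at rose by 1.68. These 14 probe sets passed in all 4 fits that left out 1 array.

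Of the 8 named falls after ANAC059 induction, 4 were of low-oxygen response genes: AT3G10040, AT1G33055, AT5G10040 and AT4G10270. All 4 had been seen among the most changed genes before that list was assembled, so this count is not independent of the list. AT3G10040 changed by -2.87 ± 0.13 SE (adjusted p = 0.00104), AT1G33055 by -2.81, AT5G10040 by -2.48, AT3G15450 by -2.33, AT1G03610 by -2.21, AT1G10140 by -2.14 and AT5G19120 by -2.12. AT4G10270 changed by -2.15, with an adjusted p of 0.000907 to 0.0646 over the 4 fits that left out 1 array, the latter without empty vector replicate 1. The unnamed probe sets 264339_at and 253161_at changed by -2.72 and -2.61. In the low-oxygen list 21 of 26 genes fell (median -1.28, camera adjusted p = 9.49e-30; adjusted p = 0.693 with an estimated correlation); 9 of the 26 had been seen among the most changed genes. The only controls of this comparison were empty vector replicates 1 and 2, from which replicate 3 of the ANAC092 set lay at -0.99 for the list. For the 17 members not seen among the most changed genes, the medians were -0.85 and -0.87 on ANAC059 induced replicates 1 and 2, against -1.29 and -1.39 for all 26, and empty vector replicate 3 lay lower, at -0.95.

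Limma called 679 probe sets after ANAC059 induction, 375 higher and 304 lower, and 143 by at least 1 on the log2 scale (42 higher, 101 lower). The groups did not overlap at 53.0% of probe sets, against 33.3% by chance for 2 arrays against 2. Leaving out empty vector replicate 1, empty vector replicate 2, induced replicate 1 or induced replicate 2 gave 161, 330, 444 and 375. In these fits the lone array was assumed to vary like the other group. Higher calls outnumbered lower ones with the deposited values, but not with quantile normalization (335 higher, 362 lower) or in any of those 4 fits (54 and 107, 120 and 210, 181 and 263, 169 and 206).

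Empty vector replicate 3, an array of plants without either inducible construct, was compared with empty vector replicates 1 and 2 of the ANAC092 set at these calls. It departed in the direction of the call for 83.2% of the 375 higher and 88.5% of the 304 lower probe sets. Both differences are taken from the same pair of arrays, and unchanged simulated groups gave 79.2% to 85.6% and 78.0% to 84.9% for as many probe sets of smallest p over 20 draws. The share of higher calls lay within that range and that of lower calls above it. The departure was at least 50% of the change for 233 higher and 130 lower calls, against simulated means of 189 and 151 and highest draws of 211 and 176. By this count the higher calls exceeded every draw, and the lower calls did not. Simulated probe sets were independent, which these are not. Among the named genes the departure reached 50% of the change for AT5G50915 (0.61), TRM28 (0.83), IQD24 (1.08), AT1G33055 (-1.73), AT5G10040 (-1.90), AT4G10270 (-2.17), AT1G10140 (-1.15), WRKY53 (0.91), PDF1.2 (-3.11), RCA (0.53) and 253161_at (-1.89). For these an effect of ANAC059 was not separated from variation between empty vector arrays. Replicate 3 departed the other way or by less for the other named genes, among them AT5G17350 (-0.50), AT1G77640 (-0.09), AT3G10040 (0.08) and 258059_at (-0.10). This comparison was chosen after the data were seen.

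Of the fixed lists, WRKY53, a WRKY factor of early senescence, rose by 0.65 ± 0.12 SE (adjusted p 0.0420 to 0.169 over the 4 fits; lost without empty vector replicate 1 or induced replicate 1 or 2), less than the departure of empty vector replicate 3 (0.91), and adjusted over the list alone 2 of 4 senescence markers were higher. SAG29 (0.16 ± 0.23 SE, adjusted p = 0.737) did not pass, and AT3G13672 rose by 0.92 ± 0.11 SE (0.00895 to 0.0723; lost without empty vector replicate 1); adjusted over the list alone 1 of these 2 earlier targets was higher. STZ, a zinc finger gene of stress responses, rose by 0.54 ± 0.10 SE (0.0480 to 0.181; lost without empty vector replicate 1 or 2 or induced replicate 2), with 1 of 3 oxidative stress genes higher and 1 lower adjusted over the list alone. PDF1.2, a defensin gene induced by jasmonate and ethylene, changed by -2.08 ± 0.38 SE (0.000656 to 0.199; lost without empty vector replicate 1 or 2, and at 0.172 with a trended robust prior), less in size than the departure of empty vector replicate 3 (-3.11), and was also lower adjusted over the list alone. AT4G04460 (0.07) and ALPHA-VPE (-0.06), which rose with ANAC092, did not pass; the difference between the inductions was not tested.

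No member of the other measured fixed lists passed over all probe sets after ANAC059 induction. Adjusted over the list alone, 1 of 2 chlorophyll breakdown genes was higher and 1 of 3 auxin response genes lower. The circadian gene GI was higher, and 1 gene each of nitrogen remobilisation and heat shock was lower. Each of these was the 1 measured gene of its list, so its p was not adjusted there. In limma 4649 of 22746 probe sets had an unadjusted p under 0.05. The lists of cell death, abscisic acid, ethylene, cell wall loosening and root markers had 0.

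Photosynthesis genes moved higher as a set after ANAC059 induction (6 measured, median 0.18, camera adjusted p = 0.0497; adjusted p = 0.713 with an estimated correlation). RCA, Rubisco activase, rose by 0.63 ± 0.10 SE (0.0474 to 0.139; lost without empty vector replicates 1 or 2 or induced replicate 2), and adjusted over the list alone 3 were higher. The list passed in 0 of 4 fits that left out 1 array, with camera adjusted p from 0.0528 to 0.0907. Autophagy genes were lower (median -0.18, adjusted p = 0.0497; adjusted p = 0.753 with an estimated correlation), with ATG8E at -1.62 ± 0.14 SE and ATG8F at -0.89 ± 0.14 SE passing and 8 not passing, and the call was lost without empty vector replicates 1 or 2 or induced replicate 2 (0.000117 to 0.398). Ubiquitin conjugation and protease genes were higher (33 measured, median 0.06, adjusted p = 0.0339; adjusted p = 0.693 with an estimated correlation), with PUB23 (0.89) and UBC16 (0.53) rising; that call was lost without empty vector replicate 1 or induced replicate 2 (0.0179 to 0.118). Vesicle transport genes of the VPS and SEC families were higher (18 measured, median 0.10, adjusted p = 0.0300; adjusted p = 0.693 with an estimated correlation), with 0 passing members in limma, and lost the call without empty vector replicate 1 or induced replicate 1 (0.0319 to 0.0714). Quantile normalization and removal of the dim probe sets each ended the calls of the photosynthesis, ubiquitin and vesicle transport lists (adjusted p 0.106 to 0.185). With the probe sets of a gene averaged, the photosynthesis and autophagy lists missed the threshold (both 0.0507). The autophagy and ubiquitin genes were named after their values were seen.

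Families that did not pass in either induction included beta-glucosidases, serine carboxypeptidase-like genes, tau glutathione transferases, expansins, xyloglucan endotransglucosylases, cytochrome P450, calmodulin-like, WRKY, bZIP, tetraspanin, auxin, defensin-like and glutamate receptor-like genes. Of the 24 lists, 16 did not pass after ANAC092 induction (adjusted p 0.0939 to 0.871 over those reported) and 19 after ANAC059 induction (0.0560 to 0.979), among the latter the chloroplast list, with a median of -0.12. Median, mean and test differed in sign for the serine carboxypeptidase-like, bZIP and defensin-like lists after ANAC092 induction, and for the serine carboxypeptidase-like, expansin, calmodulin-like and WRKY lists after ANAC059 induction, all among those not passing.

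The question of targets shared by the factors was addressed by the overlap of the calls. In both inductions 135 probe sets passed, 43 higher in both, 91 lower in both and 1 opposite, against 5.24 and 2.53 expected in the same direction for independent lists. Genes higher in both included AT3G13672 (4.34 and 0.92 for ANAC092 and ANAC059), scpl48 (3.69 and 1.05), SWEET2 (1.94 and 0.61), AT3G01830 (1.58 and 1.39) and AT4G27280 (1.38 and 1.26), and genes lower in both included AT3G10040, AT5G26200, AT5G19120 and AT3G27220; scpl48 and SWEET2 as shared genes were picked after their values were seen.

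The inductions shared empty vector replicates 1 and 2. Across probe sets the changes correlated at 0.357 with a covariance of 0.0279, and unchanged simulated groups against shared controls gave 0.407 and 0.0122. Those groups held no changed probe sets, so their 0 shared calls set no expected number for the overlap. With empty vector replicate 3 as the only ANAC092 control the correlation was -0.009 and the covariance -0.000959, with 26 probe sets higher in both, 13 lower in both and 5 opposite. With replicates 1 and 2 as the only ANAC092 controls it was 0.527, with 91 higher and 166 lower in both. For independent lists, 10.8 higher and 0.601 lower in both were expected with replicate 3 as the only control. With replicates 1 and 2 these numbers were 8.13 and 3.93. The observed same-direction counts lay above them in both fits, although the former rests on 1 control array. The controls could not be divided into parts of at least 2 arrays, so part of the overlap may come from the shared controls.

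**Figure D3:**
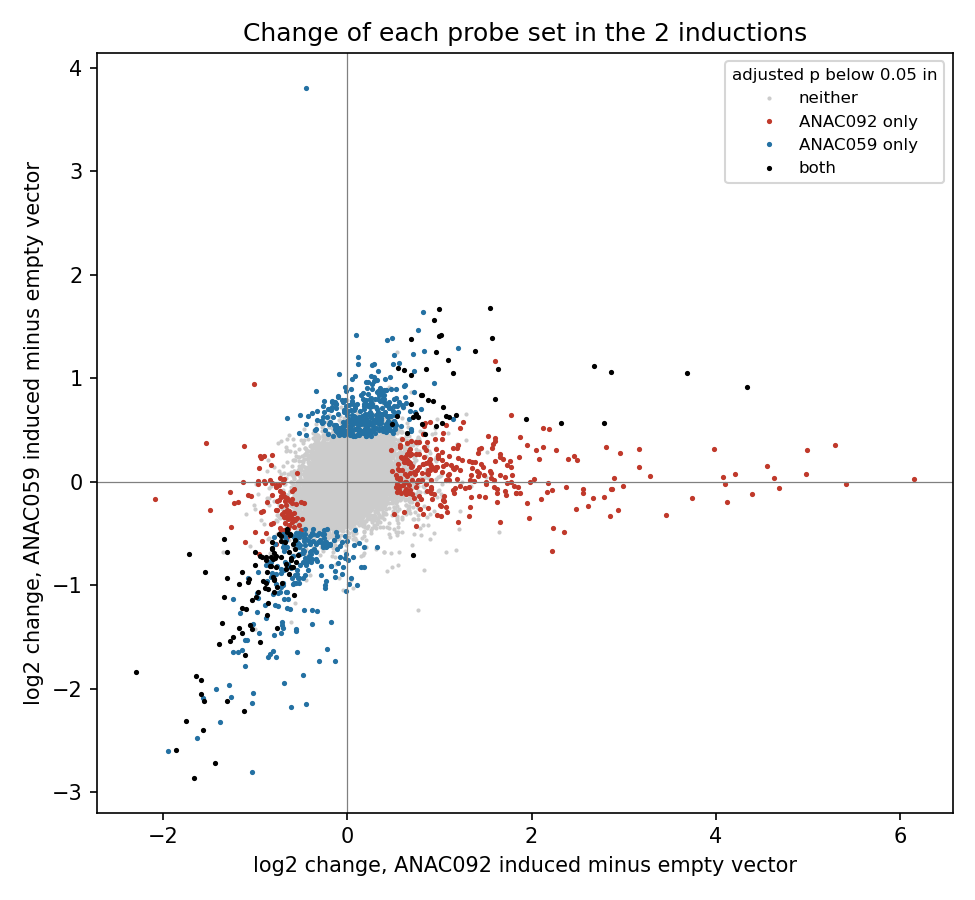
Log2 change after ANAC092 induction (x axis) against that after ANAC059 induction (y axis), each point 1 of 22746 probe sets, coloured by the comparison in which its adjusted p was below 0.05. The 135 points called in both lie mostly along the diagonal (43 higher, 91 lower, 1 opposite), and of the 12 named genes with the highest ANAC092 changes, AT3G13672 (0.92) and scpl48 (1.05) were also called for ANAC059; the axes share empty vector arrays.

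In leaf 11 of the anac092 line, compared with wild type on single arrays and so without a test, AT2G10940 was higher by 3.45 on the log2 scale, the expansin gene EXPA8 by 2.88, STOMAGEN, a peptide that promotes stomatal formation, by 2.81 and DRT100 by 2.61. AT5G20790 was at -3.01 relative to wild type, AT2G04460 at -2.79, the auxin-conjugating enzyme gene GH3.3 at -2.44, the osmotin gene OSM34 at -2.32 and ChiC at -2.27. A difference of at least 1 was seen at 223 probe sets higher and 187 lower.

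In the anac059 line the chloroplast-encoded genes rps3, ndhA and clpP were higher by 3.98, 3.38 and 2.84 and ndhI 9.84-fold, and AT3G02840, AT2G38800, and AT4G27654 by 3.31, 3.10 and 2.95; the ethylene response factor family gene ORA47 was 8.00-fold higher. AT5G20790 was at -4.09, AT2G04460 at -2.11, ChiC at -2.01 and GH3.3 at -1.89, and OSM34 was 7.98-fold lower. There were 1057 probe sets higher by at least 1 and 139 lower.

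The lines shared 77 probe sets higher and 70 lower, with 1 opposite, and their differences correlated at 0.371 across probe sets. Both were taken against the same single wild type array, so likeness of the lines was not separated from the state of that array. Values were exactly equal to wild type at 22.1% of probe sets in the anac059 line and 27.2% in the anac092 line. Chloroplast-encoded genes were higher in both lines (medians 0.31 in anac059 and 0.13 in anac092), each at percentile 100 among random lists of equal size and level. The actin 3' minus 5' signal was 2.84 in anac059, 2.55 in anac092 and 2.61 in wild type, above the 0.760 to 1.08 of the induction arrays. The GAPDH 3' minus 5' signal was 1.94 in anac059, 1.93 in anac092 and 1.97 in wild type. In the same ranking the low-oxygen list lay at percentile 78.3 in anac059 and 97.9 in anac092, with medians of 0 and 0.02. Photosynthesis lay at 74.3 and 66.2, with medians of 0 and 0.03. Since many values equal those of wild type, a median near 0 can rank high. Across the leaf set 24 lists were ranked in each line.

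Genes that a factor raises would be lower in its T-DNA line if the leaf depended on it, and this was examined across probe sets. Of 265 probe sets raised by ANAC092 with a leaf difference, 59.2% lay lower in the anac092 line (95% interval 53.1 to 65.2). The share over all probe sets with a leaf difference was 53.5%, which is within the interval. Of the raised probe sets among the 100 smallest p-values, 71.4% lay lower. The shares of all probe sets below likewise count only those with a difference. Of 162 probe sets lowered by ANAC092, 43.8% lay higher (36.1 to 51.8), against 46.5%. For ANAC059 and its line, 51.1% of 325 raised probe sets lay lower (45.5 to 56.6), below the 60.5% of all probe sets, and 62.8% of 269 lowered ones lay higher (56.7 to 68.6), above 39.5%; with quantile normalization the latter was 55.8%. In the line of the other factor, of the probe sets lowered by ANAC092, 63.0% (55.2 to 70.4) lay higher in the anac059 line against 39.5%, and of those lowered by ANAC059, 56.8% (50.7 to 62.7) lay higher in the anac092 line against 46.5%. Of the probe sets raised by ANAC059, 41.0% (35.5 to 46.6) lay lower in the anac092 line, below the 53.5% of all probe sets, and of those raised by ANAC092, 59.7% (53.6 to 65.6) lay lower in the anac059 line against 60.5%.

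Among probe sets raised by ANAC092, 17 were lower and 6 higher by at least 1 in the anac092 line, and among those lowered by ANAC092, 1 was higher and 7 lower. Among probe sets raised by ANAC059, 3 were lower and 30 higher by at least 1 in the anac059 line, and among those lowered by ANAC059, 46 were higher and 11 lower. Over all probe sets, 1057 were higher and 139 lower by at least 1 in the anac059 line (88.4% higher). In the anac092 line these were 223 and 187 (54.4% higher). Both ANAC059 counts thus leaned higher, as the anac059 array did over all probe sets. Named genes raised by ANAC092 and lower by at least 1 in the anac092 line were ChiC, AT5G38710, AT1G02470, AT5G39520, AT1G19200, AT1G08310 and AT1G74010, with leaf differences of -2.27, -2.02, -1.57, -1.36, -1.17, -1.11 and -1.01, respectively. On induction AT5G39520 rose 18.4-fold, and the others in that order by 3.97, 1.43, 2.96, 1.81, 0.80 and 2.78. These 7 were picked after their values were seen. AT5G39520 (-1.34) and ChiC (-2.01) were also lower in the anac059 line, against the same wild type array. SAG29 differed by -0.31 in the line, and AT4G04460 (4.73) and AT3G13672 (4.61) had wild type signals below the 5.76 required for leaf genes, where a fall could hardly be seen.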

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

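Differences between inductions were taken from each array's list median, and the tests of the explanations below were written before their results were seen, although the requirement that a correlation lie beyond its permutation spread was added after its value was seen. The photosynthesis list had a median change of -0.28 after ANAC092 induction and 0.18 after ANAC059 induction, with the ANAC092 induced arrays all lower (-0.45 to -0.08) and the ANAC059 induced arrays all higher (0.13 to 0.18). The autophagy list had medians of 0.41 and -0.18, with arrays at 0.31 to 0.51 and -0.30 to -0.06. Without empty vector replicate 3, a control of the ANAC092 set alone, the mean autophagy change after ANAC092 induction was 0.15 (camera adjusted p = 0.181) against 0.42 with it. The photosynthesis call was lost as well (camera adjusted p = 0.107). That loss was not particular to replicate 3, since only the fit without induced replicate 1 kept the call. The difference between the inductions was not tested in either case, and the comparisons used separately normalized sets.

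Low-oxygen response genes lay lower after ANAC092 induction than in the empty vector. A candidate explanation is the state of empty vector replicates 1 and 2, which both inductions share: replicate 3 lay almost as low as the induced arrays, and the median difference of the induced arrays to replicate 3 alone was -0.1905 (SD 0.149 over the 3 induced arrays), so the spread reaches the bound of -0.1 set for the test. A biological explanation, that ANAC092 lowers these genes, stays open as untested, since 1 control array stands against 2 and the state of single arrays cannot be told apart from the vector's own variation. The 5 called members lay below replicate 3 as well, by values of -1.71 to -0.59, although that replicate was among the controls that gave the calls.

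Chloroplast-encoded genes lay higher after ANAC092 induction. The explanation by induced replicate 2 alone is argued against by the other induced arrays, whose lower median difference to the control mean was 0.3482, against an SD of 0.123 over the control arrays. RNA integrity stays open: the deviations of the list median and of the actin 3' minus 5' signal from their group means correlated at -0.8033 over 6 arrays (rho -0.60, -0.955 without the 2 arrays farthest from the median, exact permutation p = 0.111 for r and 0.278 for rho, two-sided), which met the bound of -0.5 set against a rise with degradation but not beyond its spread, and between groups both measures were higher in the induced arrays. The GAPDH signal overlapped between the groups of the ANAC092 set (0.129 to 0.254 induced, -0.140 to 0.509 empty vector), so the difference in integrity rests on actin alone. The ANAC059 induced arrays had a raised actin signal as well (1.01 and 1.06, against 0.779 and 0.880 in their controls), with list medians of 0.17 and -0.35. This goes against RNA integrity as the cause, but these arrays lie too far apart to exclude it. An effect of ANAC092 on chloroplast transcripts is untested beyond this.

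Among probe sets differing from wild type by at least 1, the anac059 leaf array had many more higher than lower, while over differences of any size 6989 were higher and 10726 lower. The authors' scaling is argued against as the whole cause, since the lower of the ratios of higher to lower calls after centring or quantile normalization was 4.641, against 1057 higher and 139 lower with the deposited values. Without the dimmest 33.3% of probe sets the ratio was 7.235, and 1120 of the 1196 differences of at least 1 remained. That filter used the mean signal, which a high value in anac059 raises. Probe sets dim in wild type can therefore pass it, and rps3, for example, had 4.81 in wild type and 8.79 in anac059. For this reason the ratio cannot decide whether dim probe sets give the pattern. With 1 array per line, a state of that array, of the leaf sampled or of the wild type array may give the same pattern and cannot be told apart from an effect of the insertion.

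The 6 arrays of the ANAC092 set can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division called 507 probe sets and the highest other 0 with limma, although at an unadjusted p under 0.05 the others gave up to 3070 against 2734, the 3070 with empty vector replicates 1 and 2 and induced replicate 2 on one side; 1 of 10 divisions reached the real count. For gene lists the real division called 8 and the highest other 7, and 1 of 10 divisions reached the real count.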

How the results depend on the processing

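Fits with empty vector replicate 3 or replicates 1 and 2 as the only controls, and with ANAC092 induced replicates 1 and 3 averaged, were chosen after seeing the data; the cause of a change was not tested unless given. For ANAC092, the 507 calls became 226 with a log2 change of at least 1, 200 with single-gene probe sets (fewer were tested), 242 with induced replicates 1 and 3 averaged and 209 to 787 without single arrays. Array weights gave 9747, from a weight estimate that stopped before converging (weights 0.152 to 8.12), so this is not a usable count. The other settings gave 466 to 698. For ANAC059, the 679 calls became 143 with a change of at least 1, 260 with single-gene probe sets and 161 to 444 without single arrays; array weights, which converged, gave 679. Same-numbered arrays deviated together at -0.107, 0.271 and 0.0968 in the ANAC092 set and 0.0281 in the ANAC059 set. Arrays of different number did so at -0.244 to 0.202 in the ANAC092 set and -0.0281 in the ANAC059 set. With 2 arrays per group the latter is the same-number value with its sign reversed, so it adds nothing. These values do not show that the numbers pair arrays, but are too few to exclude it. With the replicate block limma called 553 and 0, the latter with 4131 at an unadjusted p under 0.05. Lists went from 8 to 0 (ANAC092) and from 5 to 0 (ANAC059) with an estimated correlation, with 2 and 1 at an unadjusted p under 0.05, to 2 to 10 and 2 to 5 without single arrays, and for ANAC059 to 2 with quantile normalization, 2 without dim probe sets and 3 with probe sets averaged. Same-direction overlap went from 134 to 237 at an adjusted p under 0.1, 39 with empty vector replicate 3 and 257 with replicates 1 and 2 as the only ANAC092 controls. Leaf differences of at least 1.5 numbered 382 in anac059 and 107 in anac092, against 1196 and 410. Opposite shares for the 100 smallest p were 71.4% (ANAC092 higher), 20% (ANAC092 lower, 5 probe sets), 20.8% (ANAC059 higher) and 79.1% (ANAC059 lower). For all probe sets lowered by ANAC059 the share was 55.8% with quantile normalization, against 62.8%. SAG29 under ANAC059, which did not pass, ranged from -0.15 to 0.46 without single arrays and reversed to -0.09 without empty vector replicate 2 and -0.15 without induced replicate 2. No gene or list value of the ANAC092 induction reversed. Signal over background was not assessed.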

Other observations

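Probe sets raised in both inductions included these genes, given by locus and picked after their values were seen: AT4G12580 (2.86 for ANAC092 and 1.06 for ANAC059), AT1G74010 (2.78 and 0.57), AT5G59845 (2.68 and 1.12), AT5G04390 (2.32 and 0.56) and AT1G58170 (1.64 and 1.09). All of the 43 probe sets raised in both also lay higher on the ANAC092 induced arrays than on empty vector replicate 3, with a median of 1.00, and the 91 lowered in both lay lower, with a median of -0.78. Replicate 3 was among the controls that gave the calls, so these counts are partly fixed by the selection.

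Calmodulin-like genes, calcium sensors of signalling, showed mixed values after induction; the genes named were picked after their values were seen. CML23 rose by 1.60 after ANAC092 induction, and after ANAC059 induction it was at 1.17 (adjusted p = 0.0669) while CML37 rose by 1.07 and CML38, also a member of the low-oxygen list, changed by -1.27. In the leaf arrays the list had a median of 0.59 in anac059 (percentile 98.7) and 0.39 in anac092 (percentile 99.8), with 5 of 7 genes higher in each. CML38 was higher by 2.55 and CML37 by 1.58 in the anac059 line. The list did not pass in either induction (camera adjusted p 0.0939 and 0.682).

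Other families differed from the bulk of probe sets on the single leaf arrays, and those given here were picked after their values were seen. UDP-glycosyltransferases had medians of -0.10 in anac059 (percentile 1.17) and -0.06 in anac092 (0.19), with 0 genes differing by at least 1. RALF-like genes had -0.16 (2.66) and 0.20 (99.98), and expansins -0.17 (0.87) and 0.07 (99.3). Tetraspanins (0.6) and vesicle transport genes (99.1) also lay far out in anac059. Percentiles describe these arrays only.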
